A study of Mus musculus with 13 samples.

How the data were processed

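Whole-genome DNA of GFP+ bone marrow cells from C57BL/6 mice aged 8 to 10 weeks was sequenced, with 1 library for each of 7 cell populations. The B-ALL (B220+), T-ALL (CD3+), AML (Mac1+Gr1+) and AUL (negative for all these markers) libraries came from 2000000 cells each, per the labels' protocols. The M-MPAL fraction (Mac1/Gr1 positive, B220 and CD3/4/8 negative), the T-MPAL fraction (CD3/4/8 positive, Mac1/Gr1 and B220 negative) and the empty control came from 1000000 cells each. Fragments of 350 bp were read as pairs of 150 bp with a planned depth of 30x, per the labels' protocols. The series lists 13 samples, of which 6 concern viral integration sites and are not analysed here.

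BWA and the mouse build mm10 are named in the submitters' processing notes, with no version. SNVs and INDELs were called with samtools and copy number changes with FREEC, and ANNOVAR added genes, repeats, segmental duplications and dbSNP build 142, per the file headers and names. Each deposited variant carries a Phred-scaled quality score, a read depth and a number of alternative reads, and the lowest deposited quality was 20. The deposited copy number tables give whole copies per region in steps of 1 kb, with 2 as the normal number, together with a confidence score that was not used here. The filters behind the deposited calls, the FREEC settings and the versions of the callers are not given in the sources used here. The AUL copy number table ended in the middle of a line: its 17 whole lines hold 15 calls on chromosome 1 and 2 on chromosome 2, so AUL was left out of the copy number comparison.

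A private variant was a call (position and alternative allele) on chromosomes 1 to 19 or X with at least 10 reads in 1 library and no call of any depth in the other 6. Variants shared by exactly 2 libraries were counted in the same way for all 21 pairs. Protein-altering variants were nonsynonymous, stop-gaining, stop-losing and splicing SNVs and exonic or splicing INDELs, by the deposited annotation. Where the annotation lists several transcripts of a gene, the protein change is given for the transcript with the farthest position. A stringent set added a quality of at least 100, at least 4 alternative reads, an alternative read share of at least 0.2 and no segmental duplication. It was chosen after seeing the data.

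With 1 library per group, no difference between groups has a replicate check, and no test of groups was made. Counts carry exact Poisson intervals and shares carry exact Clopper-Pearson intervals at the 95% level. These intervals cover counting error only, since reads without molecular identifiers are not independent molecules. The chi-square test of the 6 base change classes compares libraries, not conditions. Each gene list was described by its place among 10000 random lists of the same size matched on the number of exonic variants called in any of these libraries. Coding lengths are not in the reference table used here, so that the planned first choice of matching was not possible.

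Gene spans came from a RefSeq table of assembly GRCm38.p6. Of 872 exonic variants whose gene is in that table, 868 (99.5%) lay inside the gene's span, so its coordinates were used with those of the files. Of 137 list names, 136 distinct genes were found, since Miz1 is listed there as another name of Zbtb17. The antigen receptor loci span the first to the last gene segment of each locus in that table. Copy number starts were raised by 1 base to count from 1.

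The definitions, the comparisons, the gene lists and the alternatives named below, except those said to be later, were fixed before the data were examined. The lists were T-ALL genes (36), B-ALL genes (34), AML genes (37), DNA repair and damage response genes (31) and Myc network genes (19). The named genes are Mycn, list genes with a private protein-altering variant or inside a copy number call under 5 Mb, and all antigen receptor loci. Added to these, per library, are the 4 genes outside the lists whose private protein-altering variant had the most alternative reads, and the same for variants shared by both MPAL fractions. Genes outside the lists with such variants at different positions in 3 or more leukaemia libraries and none in the control are named too. Olfactory, vomeronasal, Zfp, Gm and Rik genes and segmental duplications were left out of these choices. Stop-losing variants, which the rule does not name, did not count for it. Of the items that these rules name, 1 is not reported here.

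The alternatives changed the depth minimum (5 or 20 reads), the quality minimum, the treatment of repeats, weak calls, dbSNP variants, clustered variants and nearby calls, the chromosomes, and the length, merging and recurrence of copy number calls. The scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested on simulated data: in 28 simulated sets of libraries, 2116 of 2116 planted SNVs were assigned to the right libraries, losses planted at 6 receptor loci were found, and 0 planted shared gains were kept as unshared.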

Results

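The series concerns acute leukaemias that arise in mice whose blood-forming cells overexpress N-Myc, a transcription factor of the Myc family. Variant and copy number calls were compared between 6 leukaemia libraries and 1 library of GFP+ cells carrying an empty construct. Each group had 1 library. The SNV tables held from 36461 calls (empty control) to 47499 calls (AUL), and the INDEL tables from 92317 (T-MPAL) to 132423 (T-ALL). At the 21857 SNVs called in all 7 libraries, the median depth was 48 reads in B-ALL, 53 in T-ALL, 49 in AML and 48 in AUL. It was 46 in M-MPAL, 47 in T-MPAL and 43 in the empty control. Of 84265 distinct SNVs, 60.3% lay in annotated repeats and 40.4% in segmental duplications.

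The first comparison asked how many SNVs each leukaemia carried that no other library showed. The labels name no matched normal DNA of each animal. Inherited and acquired variants therefore cannot be told apart in these counts, nor in the base changes and protein-altering variants below. AUL, the leukaemia without lineage markers, stood apart with 7455 private SNVs (95% interval 7287 to 7626), which was 3.37 times the 2212 (2121 to 2306) of the empty control. T-ALL had 4304 (4176 to 4435), 1.95 times the control. M-MPAL had 3199 (3089 to 3312), T-MPAL 2656 (2556 to 2759), AML 2574 (2476 to 2675) and B-ALL 2457 (2361 to 2556). The control was not the lowest in every setting: with at least 20 reads it had 1413 against 1279 in B-ALL and 1352 in AML, and outside repeats and segmental duplications 505 against 473 and 504. In the stringent set the contrast grew, because the control fell to 195 (169 to 224) while AUL kept 4545 (4414 to 4679), 23.3 times as many. M-MPAL then had 1274, T-ALL 1194, T-MPAL 734, AML 228 and B-ALL 222. The low counts of AML and B-ALL depend on each other: when AML was not asked to lack the variant B-ALL had 583 (537 to 632), and AML without B-ALL had 636 (588 to 687). In the same way M-MPAL had 1815 and T-MPAL 1289 without the other fraction, while the control reached at most 228 (199 to 260) with 1 other library left out. This count was added after the data were seen. The median alternative read share of these stringent private SNVs was 0.471 in AUL and 0.471 in T-MPAL, against 0.389 in B-ALL and 0.325 in the empty control. Variants listed in dbSNP made up 4.29% of the stringent private SNVs of AUL and 24.5% of those of T-ALL. The control shares its protocol with the MPAL fractions alone, so that for the leukaemias of the other protocol (AUL, AML, T-ALL and B-ALL) the protocol and the difference from the control cannot be told apart. Against the other 3 libraries of its own protocol alone, AUL had 8687 private SNVs, T-ALL 5364, B-ALL 3431 and AML 3402. Within the protocol of the control, M-MPAL had 5274 and T-MPAL 4997 against 4542 in the control.

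**Figure D1:**
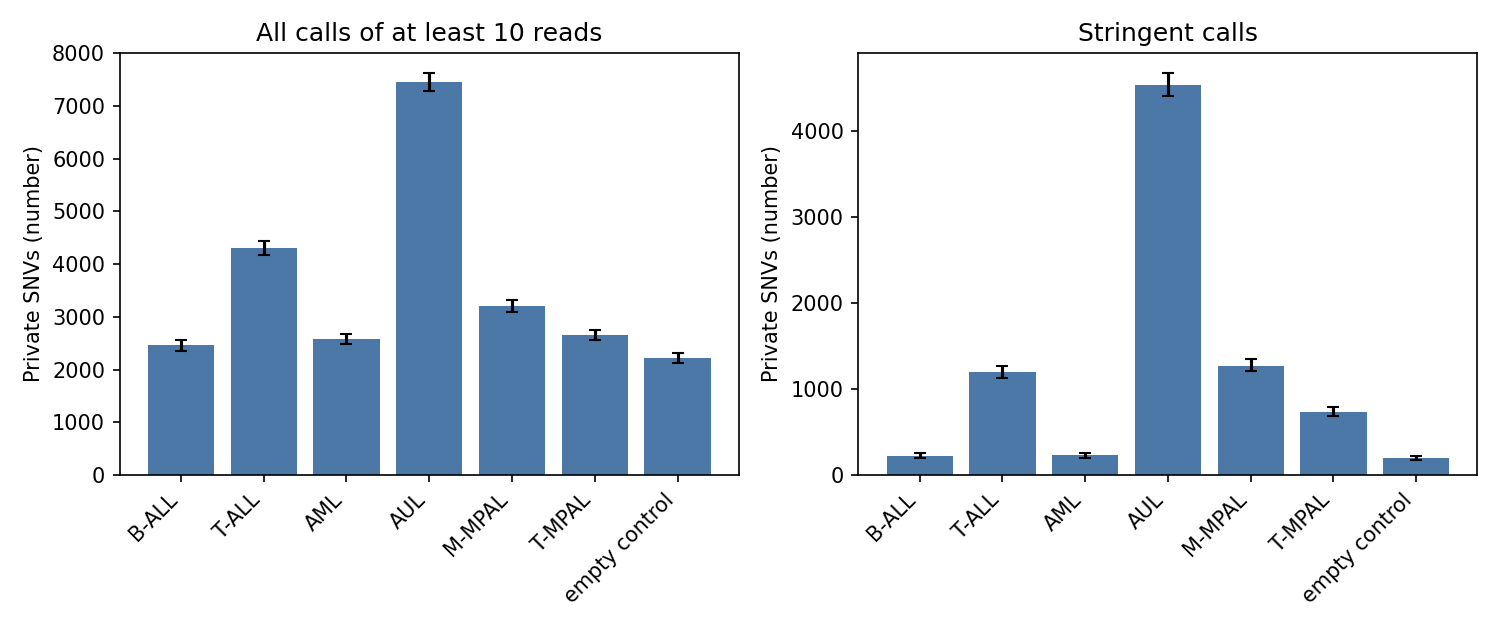
Private SNVs per library (number of calls, y axis) among all calls of at least 10 reads and in the stringent set, with exact Poisson 95% intervals as error bars. AUL has the highest bar in both panels, 7455 and 4545, and the empty control the lowest, 2212 and 195.

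The kinds of base change differed between libraries. C>T changes made up 49.1% (48.0 to 50.3) of the private SNVs of AUL and 39.1% (37.4 to 40.9) of those of M-MPAL, against 30.97% (29.0 to 32.9) in the empty control. The share was 28.8% in T-MPAL, 27.3% in T-ALL, 24.2% in AML and 23.6% in B-ALL. T>C changes were the most frequent class in T-ALL (31.8%), AML (30.1%) and B-ALL (29.5%), while T>A changes reached 19.9% in the empty control. The stringent set did not bear this out: C>T changes led T>C changes in T-ALL (33.7% against 27.9%), AML (28.9% against 22.4%) and B-ALL (30.6% against 22.5%), and T>A changes in the control fell to 9.23%. There C>T changes made up 61.2% in AUL, 45.4% in M-MPAL, 32.0% in T-MPAL and 44.6% (37.5 to 51.9) in the control, so that M-MPAL no longer stood above the control. The chi-square statistic over the 7 libraries was 1787.7 with 30 degrees of freedom, and over the 6 libraries without AUL it was 740.3 with 25 (p = 4.47e-140). It compares these libraries, whose neighbouring SNVs are not independent.

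Private protein-altering variants were looked at next, first in genes known from human leukaemia. B-ALL carried a missense variant in Trp53, the p53 tumour suppressor, R210C in exon 6 (chromosome 11, position 69588703), on 8 of 27 reads (29.6%, 13.8 to 50.2). AUL carried N564D in exon 13 of Pik3r1, which encodes the regulatory subunit of phosphoinositide 3-kinase, on 7 of 22 reads (31.8%, 13.9 to 54.9), at chromosome 13, position 101687186. M-MPAL carried a stop codon, Q1643X in exon 8, in Setd2, a histone methyltransferase gene, on 10 of 33 reads (30.3%, 15.6 to 48.7), at chromosome 9, position 110564658. These 3 remained in the stringent set. No list gene had a private protein-altering variant in the empty control. That does not set the control apart, since matched random lists had a median of 0 or 1 such hits over the 6 leukaemia libraries together.

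Other list genes had weaker calls. In AML, splice-site INDELs in Ezh2, the methyltransferase of Polycomb repressive complex 2, and in Fanca, of the Fanconi anaemia DNA repair pathway, each rested on 4 of 19 reads inside a repeat. At the position in Ezh2 the empty control had another INDEL on 4 of 15 reads and T-MPAL on 5 of 15. A frameshift in Pole, the catalytic subunit of DNA polymerase epsilon (C1442fs), had 3 of 24 reads. Kmt2d, another histone methyltransferase gene, had in-frame deletions inside repeats in M-MPAL (5 of 33 reads) and at another position in T-MPAL (5 of 42 reads). Pik3r1 had a further in-frame deletion in AUL on 3 of 27 reads. Together these were 8 pairs of a list gene and a leukaemia library, and the stringent set kept 3 of them.

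By list, the T-ALL genes had 3 such pairs, the B-ALL genes 4, the AML genes 2 and the DNA repair genes 3, with some genes on several lists. The pairs did not follow the leukaemia that a list is named for. The T-ALL library had 0 pairs on every list, and the T-ALL genes had 1 each in B-ALL, AML and AUL. Of the B-ALL genes, 1 pair was in B-ALL, 2 were in M-MPAL and 1 in T-MPAL. Trp53 in B-ALL counts for each of these lists. Of the 10000 matched random lists, 94.3% had fewer pairs than the T-ALL genes, 97.4% fewer than the B-ALL genes, 98.4% fewer than the AML genes and 99.3% fewer than the DNA repair genes. The exonic variants used for the matching include the private ones that make a pair, so the matching is not independent of the pairs. Splicing calls, as in Ezh2 and Fanca, make a pair but were not counted for the matching. These percentiles describe these libraries and all calls alone: the stringent set left 2 pairs for the T-ALL genes, 2 for the B-ALL genes, 1 for the AML genes and 1 for the DNA repair genes, and with lists matched on gene length the AML genes were at 92.3%. The Myc network genes, which include Mycn itself, Myc and Max, had 0 pairs.

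Across all genes, AUL had 66 private protein-altering variants (51.0 to 84.0), T-MPAL 36, T-ALL 34, M-MPAL 27, B-ALL 27 and AML 23, against 31 (21.1 to 44.0) in the empty control. The stringent set kept 31 in AUL, 11 in T-MPAL, 9 in T-ALL, 9 in M-MPAL, 5 in AML, 2 in B-ALL and 5 in the control. Without the partner library these were 10 in AML, 6 in B-ALL, 17 in M-MPAL and 19 in T-MPAL, and the control had at most 6 with 1 other library left out. Outside the lists, the best covered private variants of AUL were a splice-region SNV in Acvrl1, a receptor of the TGF-beta family, on 25 of 34 reads, and P1115H in Dhx38, a splicing helicase, on 25 of 35 reads. Ppp2r2c, a regulatory subunit of protein phosphatase PP2A, had F73C on 16 of 33 reads and Lce1a2, a gene of the cornified envelope, S122N on 15 of 33. In M-MPAL, Smarca4, the ATPase of the SWI/SNF chromatin remodeller, had E535K on 25 of 53 reads. Rrs1, needed for ribosome assembly, had the frameshift A194fs on 17 of 48 reads, with a quality of 75 that left it outside the stringent set. Abcd2, a peroxisomal transporter, had A83T on 17 of 50. AML had another Smarca4 change, D1225H, on 13 of 28 reads, a gene named here for AML after its values were seen. T-MPAL had G655S in Frmpd4, a synaptic scaffold (15 of 30 reads), S163Y in Cd180, a Toll-like receptor relative of B cells (12 of 26), and L21P in Tulp3 (10 of 27).

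T-ALL had Q960R in Thbs1, the matrix protein thrombospondin (27 of 64 reads, listed in dbSNP), and R1077W in the export transporter Abcc2 (19 of 38). Thbs1 had further private missense calls in T-ALL. F951V (25 of 62) lay at position 118122954, close to Q960R at 118122982, and A69P (14 of 39) had a quality of 30.8. The median depth of the stringent private SNVs of T-ALL was 31 reads. B-ALL had Q183H in Fmo6 (9 of 24 reads), P88R in Asmt (7 of 31) and a splice-site INDEL in the calcium channel gene Cacna1g (6 of 15, in a repeat where the control had another INDEL at the same position, 5 of 16). AML had D581N in Rgsl1 (14 of 23 reads) and M1472L in the mucin gene Muc4 (13 of 42). The calls in Asmt (quality 53) and Muc4 (quality 33.5) lay outside the stringent set. The empty control had A87D in Cyp2b10 (10 of 44), A11T in Eya2 (9 of 33), the stop codon S80X in Dhrs7 (7 of 27) and a splice-site INDEL in Layn inside a repeat (8 of 13), where AUL had another INDEL at the same position (6 of 12). Mroh2a was the gene with such variants in 3 leukaemia libraries (B-ALL, T-ALL and T-MPAL) and none in the control, and Ugt1a exons next to it were among the best covered private variants of AML, M-MPAL and T-ALL. That part of chromosome 1 (88212001 to 88311000) was called at 10 to 13 copies in all 7 libraries, at 12 in the control, so these variants lie in sequence with far more reads than a normal gene.

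Among all calls, INDELs did not separate the leukaemias from the control. The empty control had 29261 private INDELs (28927 to 29598), within the range of the leukaemias from 24780 in M-MPAL to 36503 in T-ALL. Repeats held 97.9% of those of the control and from 97.3% (M-MPAL) to 97.8% (B-ALL) of those of the leukaemias. In the stringent set T-ALL had 2979, M-MPAL 2372, AUL 2018, AML 1954, T-MPAL 1706 and B-ALL 1487, against 1580 (1503 to 1660) in the control. All leukaemias but B-ALL lay above the interval of the control there, although the interval of T-MPAL (1626 to 1789) overlapped it. These counts leave out 389 stringent INDELs that B-ALL shared with AML alone and 437 that the MPAL fractions shared with each other alone. The place of B-ALL therefore depends on AML.

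The MPAL comparison asked how far the myeloid and the T-lymphoid fraction of mixed-phenotype leukaemia carry the same variants. M-MPAL and T-MPAL shared 910 SNVs (852 to 971) that no other library had, the highest count of the 21 pairs. Among their shared protein-altering variants were R32K in Ttpa, the vitamin E transfer protein (13 of 24 reads in M-MPAL, 15 of 28 in T-MPAL), and D742Y in Csmd1 (16 of 27 and 10 of 21). G226D in Pdhx, a part of the pyruvate dehydrogenase complex, had 14 of 26 and 8 of 14 reads, and R125H in the sialidase gene Neu3 had 10 of 21 and 10 of 16. Both fractions together had 10 shared protein-altering variants, none in a list gene. Whether both fractions came from the same mouse is not in the labels. Inherited and acquired variants therefore cannot be told apart among the SNVs that both fractions share. Outside the planned comparison, B-ALL and AML shared 809 SNVs (754 to 867), ahead of the third pair, T-ALL and AML, with 392. In the stringent set the MPAL fractions shared 486 (444 to 531) and B-ALL and AML 322 (288 to 359), while the third pair, T-ALL and AUL, shared 32 (21.9 to 45.2). With calls of 5 or more reads B-ALL and AML came first, with 1021 against 1006. For INDELs the MPAL pair came ninth with 3160 (3051 to 3272), behind T-ALL and AML with 4476. In the stringent set the order of the INDEL pairs changed. The MPAL pair then came first with 437 (397 to 480) and B-ALL and AML second with 389 (351 to 430), ahead of T-ALL and the empty control with 87.

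**Figure D2:**
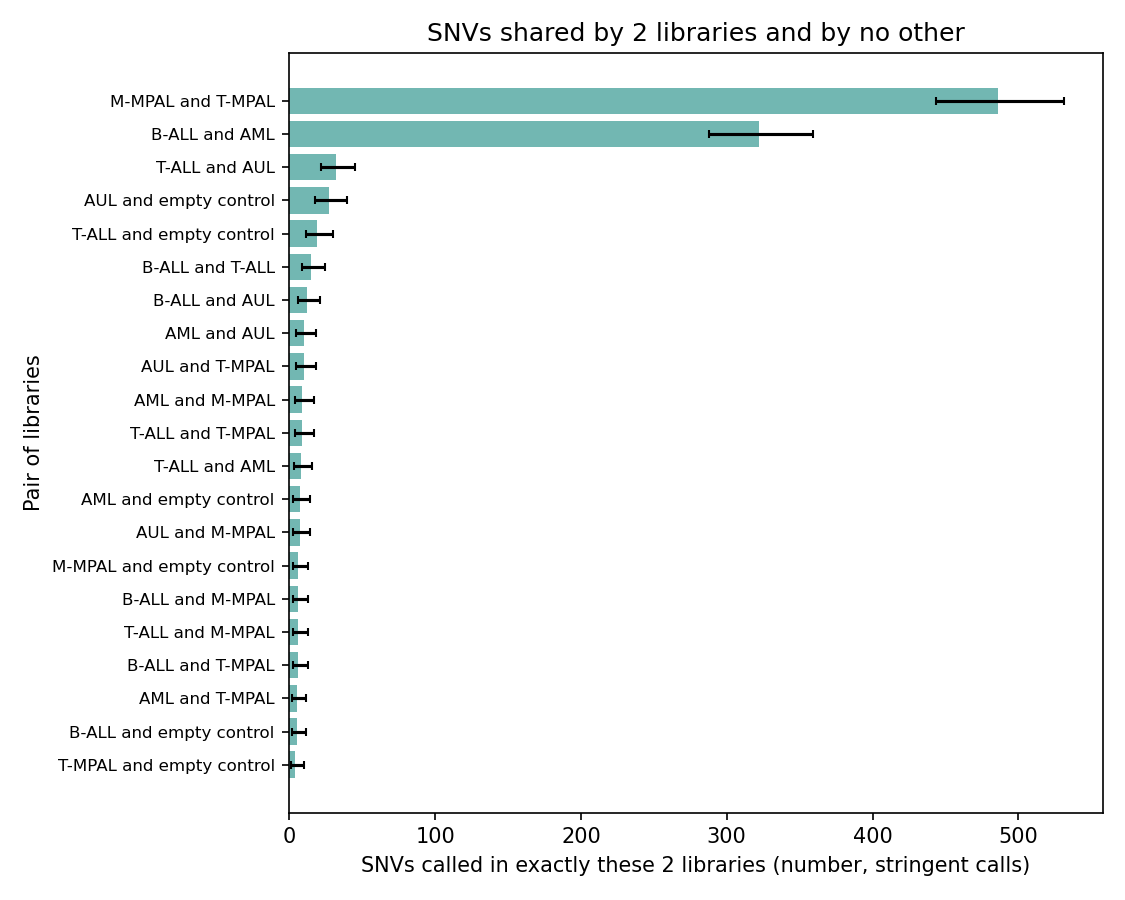
SNVs of the stringent set called in exactly the 2 named libraries (number, x axis) for all 21 pairs (y axis), with exact Poisson 95% intervals. M-MPAL with T-MPAL (486) and B-ALL with AML (322) lie far above the next pair (32).

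Shared SNVs of the MPAL fractions in the stringent set had alternative reads at a median share of 0.485 in M-MPAL and 0.5 in T-MPAL over the 394 sites outside chromosomes 15 to 19 and X. On chromosome 15 the shares ran in opposite directions, so that 15 of 19 sites lay above 0.5 in one fraction and below it in the other. On chromosome 18 the median was 1.00 in T-MPAL and 0.529 in M-MPAL over 13 sites, and on chromosome 19 it was 1.00 and 0.532 over 6 sites. On the X chromosome it was 0.524 in T-MPAL and 0.967 in M-MPAL over 10 sites. These chromosomes were singled out after their values were seen.

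**Figure D3:**
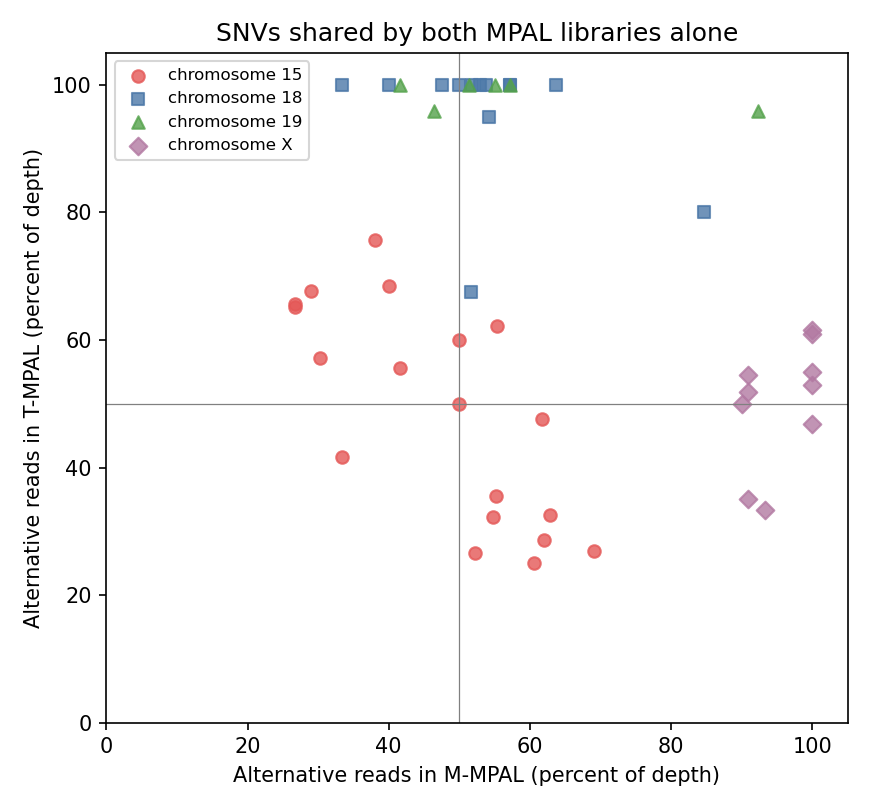
Alternative reads (percent of depth) in M-MPAL (x axis) and T-MPAL (y axis) at SNVs of the stringent set shared by these libraries alone, 1 point per SNV, on chromosomes 15, 18, 19 and X. Chromosome 15 points run from upper left to lower right, while 17 of the 19 points of chromosomes 18 and 19 lie above 90% in T-MPAL.

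Copy number calls asked which chromosomes each leukaemia had gained or lost. Both MPAL fractions had gained chromosome 15, with 99.6 Mb at mostly 3 copies in M-MPAL and 100.6 Mb in T-MPAL. All 6 list genes there lay in the gain: Myc, the cytokine receptor gene Il7r, the acetyltransferase gene Ep300, the cohesin gene Rad21, the DNA repair gene Xrcc6 and Kmt2d. AML had gained 94.4 Mb and B-ALL 69.0 Mb of chromosome 16, with Runx1, a master transcription factor of blood formation, Crebbp, an acetyltransferase gene, the repair kinase gene Prkdc, Usp7 and the pre-B receptor gene Vpreb1. B-ALL had also lost 57.7 Mb of chromosome 19 to 1 copy, with the kinase gene Jak2 and the B-cell adaptor gene Blnk, which are list genes named after their values were seen. M-MPAL had 149.2 Mb of the X chromosome at 1 copy, and the sex of the mice is not given in the sources used here. T-MPAL had 51 gains on chromosome 17 that summed to 7.18 Mb. In the empty control all gains summed to 6.52 Mb and all losses to 0.981 Mb, and in T-ALL to 2.08 Mb and 1.00 Mb.

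The number of gains was 239 in B-ALL, 139 in T-ALL, 245 in AML, 302 in M-MPAL, 376 in T-MPAL and 220 (192 to 251) in the empty control. Losses numbered 15, 7, 1, 37, 23 and 22 (13.8 to 33.3) in the same order. Whole-chromosome changes were cut into many calls, and 34 of the 242 control calls were found in all 6 complete tables, so that the counts rank no library. Small losses of at least 50 kb to 1 copy, chosen after their values were seen, included Bard1, a partner of the Brca1 repair protein, and Mdga2 in T-ALL, and the phosphatase gene Ptprg in AML. The empty control had such a loss of 119 kb too, over Clk3, Edc3 and Arid3b.

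**Figure D4:**
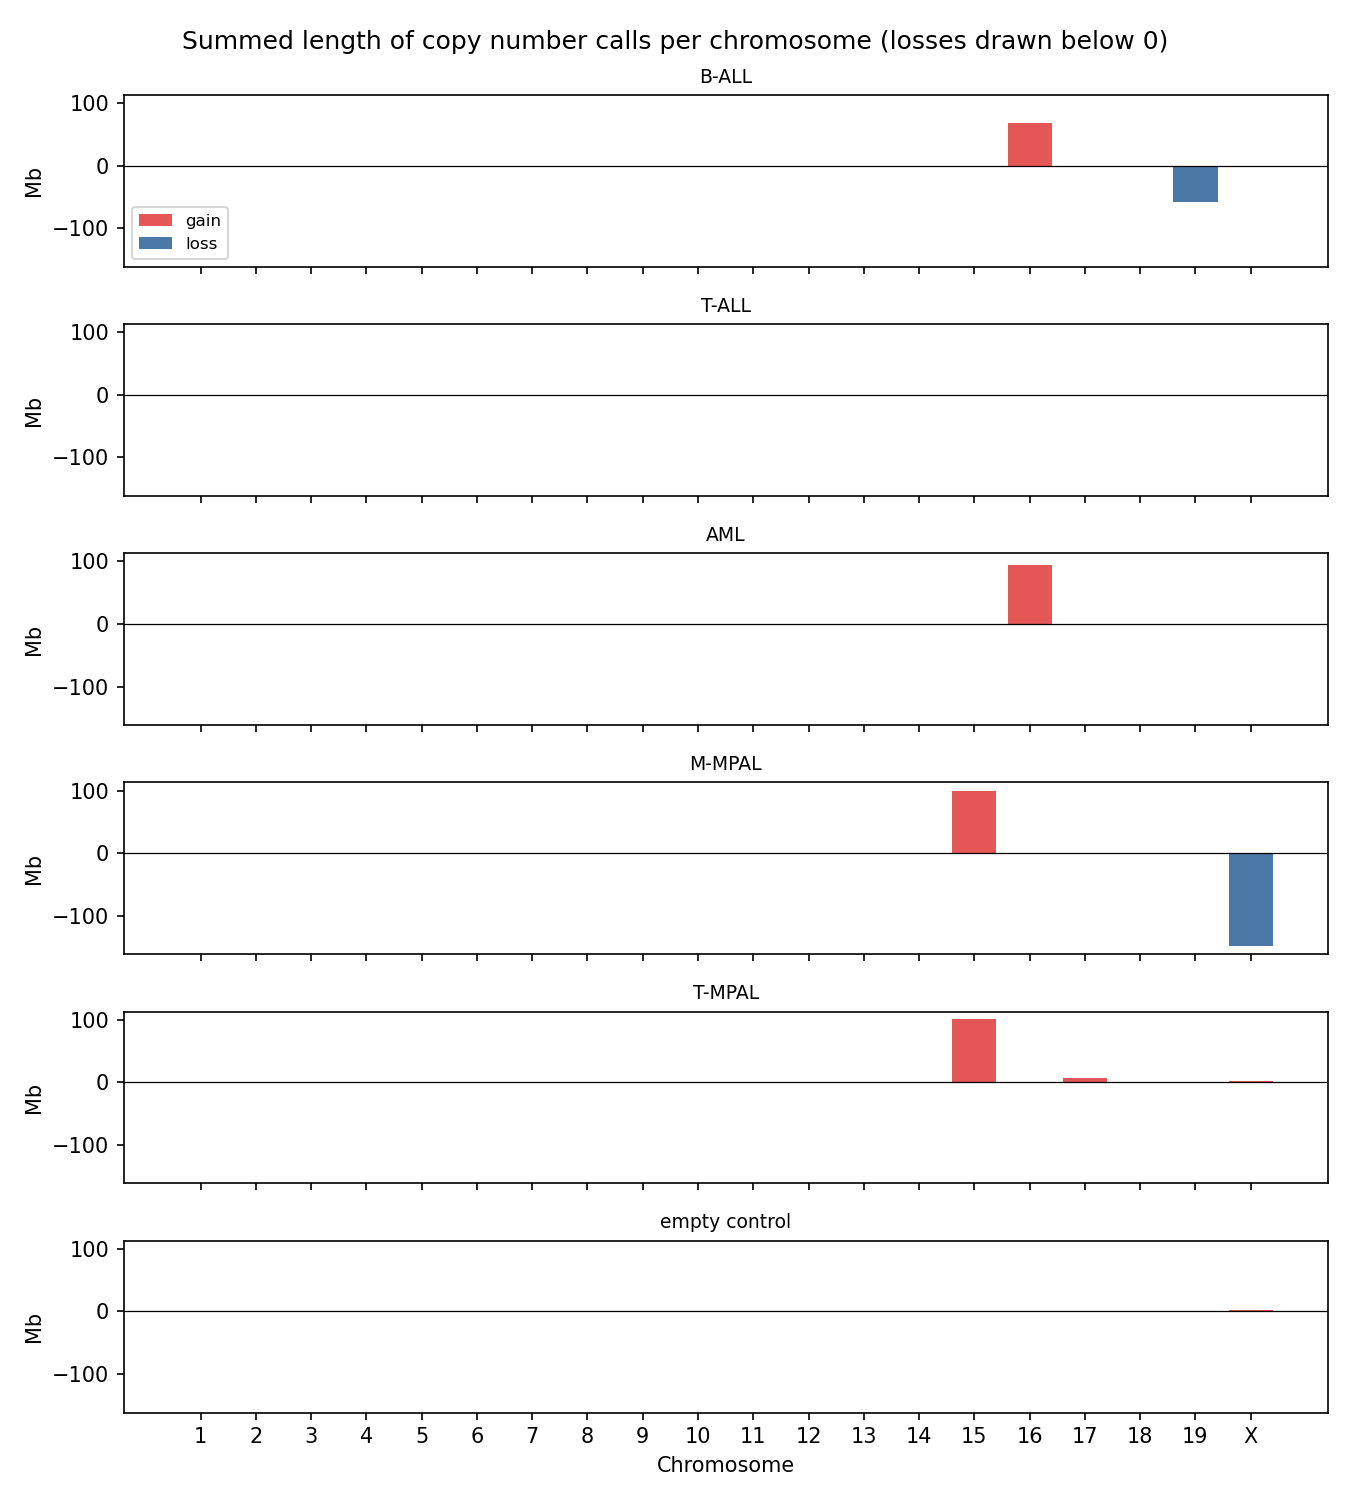
Summed length of copy number calls (Mb, y axis) per chromosome (x axis) in the 6 libraries with a complete table, gains above 0 and losses below. Chromosome 15 is gained in M-MPAL and T-MPAL, chromosome 16 in B-ALL and AML, chromosome 19 is lost in B-ALL and the X chromosome in M-MPAL.

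Antigen receptor loci lose DNA when lymphocytes rearrange them, which gives a view of lineage apart from surface markers. T-ALL had a loss of 458 kb to 1 copy (chromosome 6, 41114001 to 41572000) that covered 444371 bases of the T-cell receptor beta locus Trb, and had lost 21 kb of the gamma locus Trg (chromosome 13, 19186001 to 19207000). T-MPAL had lost 161 kb of the alpha and delta locus Tra/Trd to 0 copies (chromosome 14, 53962001 to 54123000). M-MPAL, sorted as its myeloid counterpart, had no call at any of the 6 loci, nor had the empty control. B-ALL and AML had the light chain locus Igl inside their chromosome 16 gain. No call touched Igh or Igk in any complete table, B-ALL included. Elsewhere B-ALL had losses called at 1 copy, such as 195 kb on chromosome 6. A loss of 1 allele in part of the cells may still be missed by whole copy numbers.

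Mycn, the gene that was overexpressed, lies on chromosome 12 (12936093 to 12941836). In M-MPAL and T-MPAL it carried the same 3 synonymous exonic SNVs, R124R in exon 2 and G307G and Q390Q in exon 3, all listed in dbSNP. Alternative reads over the 3 sites were 29 of 109 (26.6%, 18.6 to 35.9) in M-MPAL and 68 of 150 (45.3%, 37.2 to 53.7) in T-MPAL. B-ALL, T-ALL, AML, AUL and the empty control had no SNV in Mycn, no library had an INDEL there, and none of the 6 complete copy number tables had a call there. Calls list variants alone, so the depth over Mycn in the other 5 libraries is unknown.

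The protocols of the 4 earlier and 3 later libraries differ in cell number. SNVs called in all 4 earlier libraries and no later one numbered 299, and those called in all 3 later libraries and no earlier one 167. The stringent set kept 27 and 20. For INDELs the numbers were 571 and 783, an order that turned in the stringent set (44 and 11) and outside repeats and segmental duplications (25 and 7).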

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

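The tests in this part were chosen after the results were seen, except the odds ratio for chromosomes 18 and 19, whose prediction was written before it was computed.

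AUL had more reads on chromosome 15 than its other chromosomes, a signal from the variant tables, since its copy number table is not complete. At SNVs called in all 7 libraries outside segmental duplications, its depth there was 1.34 times (95% bootstrap interval over blocks of 1 Mb, 1.25 to 1.39) that of the libraries without a large call on the chromosome, AUL itself left out. The highest value of any autosome in the empty control was 1.09, with an upper bound of 1.16. The measure was changed after its first run, in which all other libraries were the reference and sites were not grouped into blocks for the median: chromosome 15 of AUL was then at 1.27 (1.15 to 1.28), whose lower bound did not pass the 1.18 of the control. The final measure gave 1.30 and 1.49 on chromosome 15 of M-MPAL and T-MPAL and 1.30 and 1.33 on chromosome 16 of B-ALL and AML, where the copy number tables hold 3 copies. Of the 206 stringent private SNVs of AUL on chromosome 15, 24.3% had a share between 0.4 and 0.6, against 67.5% of 3813 on the autosomes other than 12 and 15. Chromosome 12 of AUL was at 1.16 (1.08 to 1.21), which did not pass the bound of the control.

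Both MPAL libraries carried the same 3 SNVs in Mycn exons. A heterozygous variant in every cell of M-MPAL predicts alternative reads at about 50%, but they were at 26.6% (18.6 to 35.9) there, while T-MPAL was at 45.3%. Reads of another Myc family gene placed on Mycn would show in every library, but the 4 other leukaemia libraries and the empty control had 0 calls there. A heterozygous variant of the endogenous gene in part of the cells and added Mycn copies whose sequence differs from the reference cannot be told apart. Reference reads per site, 26.7 in M-MPAL and 27.3 in T-MPAL, were above the highest of the 23 other shared SNVs of chromosome 12 (22 and 21), and so were the 50 reads per site of T-MPAL (highest 34), but not the 36.3 of M-MPAL (highest 41). Depth varies between sites, however: of 252 shared SNVs outside repeats on the autosomes other than 15 and 17 to 19, 10 (3.97%, 1.92 to 7.18) had as many reference reads in both libraries and 9 were as deep in T-MPAL. Among 409 stringent sites of these chromosomes these were 3 and 5. The test of the spread between sites replaced a first one that used counting error alone. The sequence of the introduced Mycn was not used here, and why the 4 other leukaemia libraries lack these SNVs was not tested.

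Read shares of SNVs common to both MPAL libraries differed by chromosome. Counting noise does not give the relation on chromosome 15, where the shares in both libraries had Spearman's rho of -0.71 over 19 sites, against 0.14 over 410 sites of the autosomes other than 15 and 17 to 19. A single gain in a common ancestor puts a site on the same side of 0.5 in both libraries, but 15 of 19 sites lay on opposite sides (78.9%, 54.4 to 93.9), so separate gains of different copies of the chromosome in each fraction may be considered. Loss of 1 allele of chromosomes 18 and 19 in T-MPAL predicts that SNVs of M-MPAL are missing there from T-MPAL more often, and the odds ratio was 1.70 (1.01 to 2.999), a bound that barely excludes 1, with the depth of T-MPAL at 0.999 and 1.01 times that of the others. Inherited differences between 2 animals remain open for chromosomes 18, 19 and X, since the labels do not say whether both fractions came from the same mouse.

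B-ALL and AML shared SNVs that no other library had. Mapping errors in repeated sequence do not account for them, since 171 (146 to 199) stringent SNVs remained outside repeats and segmental duplications, against 18 (10.7 to 28.4) for the highest pair other than the MPAL fractions. A minor admixture of one leukaemia in the other library would give low shares in 1 of them, but over 235 shared sites, taken outside repeats with no minimum share and reaching down to 0.133 in B-ALL, the median share was 0.360 in B-ALL (0.344 to 0.375) and 0.438 in AML. Inherited heterozygous variants in every sequenced cell would give equal shares, yet B-ALL lay below AML by a median difference of -0.0607 (-0.0806 to -0.0409), against -0.0111 (-0.0358 to 0) between the MPAL fractions. The interval of the MPAL fractions reaches 0, so that inherited variants remain open for the SNVs shared by those fractions. A common ancestor cell, or inherited variants of a common donor diluted by other cells, may remain, and both libraries also share a gain of chromosome 16.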

How the results depend on the processing

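The stringent set, the comparison within a protocol, the length-matched random lists, the counts without a partner library and all settings for the SNVs shared by B-ALL and AML were chosen after seeing the data. The 67 results had 452 alternative values. The order of the libraries was not the same in every setting: the empty control had fewer private SNVs than B-ALL and AML in the main setting, but more than both at a depth of 20 reads and without repeats. AUL had the highest C>T share in all 12 settings, and the MPAL pair ranked first for SNVs in 11 of them, the exception being a depth of 5 reads, where B-ALL and AML shared 1021 against 1006. Of the values of single genes, libraries or secondary counts, 130 stayed within their bounds and 96 moved, 69 to lower and 27 to higher values. Of the values that answer a comparison, 129 stayed within their bounds and 97 moved, as follows. For counts of private SNVs these bounds were wider than the counting intervals, so a count that stayed can differ by more than counting error. Within its protocol alone, AUL counted as staying with 8687, against 7455 (7287 to 7626) in the main setting. B-ALL did so with 3431, against 2457 (2361 to 2556). Each filter removes calls by construction, and beyond that the cause was not tested. No paired analysis was possible because each group has 1 library.

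A minimum depth of 20 reads left 1279 private SNVs in B-ALL, 1352 in AML and 1413 in the empty control, so that the control passed both. Private INDELs fell to 54018 in the leukaemias and 9470 in the control, MPAL-shared SNVs to 577 and INDELs to 643, and INDELs of the 3 later and 4 earlier libraries to 147 and 52. The C>T share of AUL was 55.0%. A minimum depth of 5 gave 3855 private SNVs in B-ALL, 4061 in AML and a C>T share of 44.1%.

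A quality of at least 100 left private SNVs at 281 (B-ALL), 1312 (T-ALL), 302 (AML), 4786 (AUL), 1371 (M-MPAL), 801 (T-MPAL) and 268 (control), private INDELs at 13278 and 1677, and protein-altering variants at 73 in the leukaemias and 5 in the control. MPAL-shared SNVs were 537 and INDELs 456, B-ALL and AML shared 357 SNVs, and the C>T share was 61.0%.

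Without repeats and segmental duplications private SNVs were 473 (B-ALL), 1715 (T-ALL), 504 (AML), 3019 (AUL), 1013 (M-MPAL), 689 (T-MPAL) and 505 (control), private INDELs 3958 and 568, and protein-altering variants 121 and 11. MPAL-shared SNVs were 301 and INDELs 60, B-ALL and AML shared 256 SNVs, and the C>T share was 54.7%. SNVs of the earlier and later libraries alone were 54 and 21, INDELs 25 and 7, and list gene pairs 4.

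The stringent set left private SNVs at 222 (B-ALL), 1194 (T-ALL), 228 (AML), 4545 (AUL), 1274 (M-MPAL), 734 (T-MPAL) and 195 (control), private INDELs at 12516 and 1580, and protein-altering variants at 67 and 5. MPAL-shared SNVs were 486 and INDELs 437, B-ALL and AML shared 322 SNVs, list gene pairs were 3 and the C>T share was 61.2%. With the partner library not counted (the other MPAL fraction, or AML for B-ALL and the reverse), private SNVs of this set were 583 (B-ALL), 636 (AML), 1815 (M-MPAL) and 1289 (T-MPAL).

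At least 4 alternative reads and a share of 0.2 gave a C>T share of 50.3%, 5 list gene pairs and 18 protein-altering variants in the control. Without dbSNP variants AML had 1673 private SNVs and AUL a C>T share of 52.0%. Without variants within 1 kb of another, T-ALL had 2713 private SNVs and AUL a C>T share of 51.5%. With no call within 10 bases in another library, private INDELs were 92808 in the leukaemias and 15268 in the control, and MPAL-shared INDELs 1944.

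Within a protocol alone, private SNVs were 5274 (M-MPAL), 4997 (T-MPAL) and 4542 (control), private INDELs 268206 and 51643, and protein-altering variants of the control 53. MPAL-shared SNVs were 4407 and INDELs 10003, B-ALL and AML shared 1498 SNVs at rank 4, and the C>T share of AUL was 47.0%. Fewer libraries to be absent from raise these counts by construction.

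Calls of at least 50 kb left 454 gains and 40 losses in the 5 leukaemias with a complete table and 27 gains and 3 losses in the control. Calls not found in another of the 6 complete tables left 164 gains in the leukaemias and 144 in the control, and 3 receptor calls. Merging calls within 10 kb gave 444 gains in the leukaemias, and 2 receptor calls lay wholly inside their locus. With lists matched on gene length, 98.3% of random lists had fewer pairs than the T-ALL genes, 99.7% than the B-ALL genes, 92.3% than the AML genes and 98.1% than the DNA repair genes. The median depth of 43 to 53 reads holds for SNVs called in all 7 libraries. It was lower at stringent private SNVs, from 21 in AML to 31 in T-ALL, and at private INDELs, from 16 in AML to 17 in T-ALL. Subclones with a low share of reads are missed at such depths, and the AUL copy number is limited to its depth at SNVs.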

Other observations

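None of the values in this part was planned as a comparison, and no test was made on them.

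Chromosome 15, which holds Myc, the close relative of Mycn, was raised in depth or copy number in AUL, M-MPAL and T-MPAL, while B-ALL, T-ALL and AML were at 0.964, 0.965 and 0.957 times the depth of the others there. Chromosome 16, with Runx1, was gained in B-ALL and AML alone by the same measure. T-MPAL was at 1.11 (1.07 to 1.21) on chromosome 17, where its copy number table holds 51 separate gains. B-ALL was at 0.633 (0.528 to 0.679) on chromosome 19 and M-MPAL at 0.535 (0.513 to 0.571) on the X chromosome.

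Among the SNVs shared by B-ALL and AML were 9 protein-altering ones. They included L1155V in Pik3c2b, a class II phosphoinositide 3-kinase gene, on 7 of 22 reads in B-ALL and 8 of 23 in AML, and R112C in Slc45a4 on 7 of 23 and 14 of 32. Neither lay in a list gene, and both are named after their values were seen. The MPAL fractions shared S106R in Atg5, a gene of autophagy, on 7 of 19 and 8 of 21 reads, named in the same way.

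Stop codons among the private SNVs of AUL numbered 3, including S398X in the transporter gene Abcc12 on 6 of 15 reads. M-MPAL had G818X in the leptin receptor gene Lepr on 7 of 21 reads beside that in Setd2. SNVs called in all 6 leukaemia libraries and not in the empty control numbered 1605, of which the stringent set kept 203. At the SNVs called in all 7 libraries the control had the lowest median depth. Over all calls of each library AUL was lower, with 35 reads against 37.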
